A study of Homo sapiens with 8 samples.

How the data were processed

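Read counts per gene were used as deposited by the authors, as raw integers that, per the submitters' processing notes, featureCounts of Subread 2.0.1 had made from HISAT2 2.1.0 alignments to GRCh38. TPM were likewise used as deposited, per the file headers, and served only in an alternative fit. The tool that made them is not given in the sources used here. Per the same notes, base calls had been converted with bcl2fastq and reads had been trimmed with fastp 0.20.0 and inspected with FastQC 0.11.9. Per the labels' protocols, libraries were made with a stranded poly(A) kit (TruSeq Stranded mRNA) and sequenced as 150-bp pairs on a NovaSeq instrument. The annotation release, the strand setting and the handling of reads with several alignments are not given in the sources used here, so the values of genes that overlap others on either strand, or that have near-identical copies such as ferritins, metallothioneins and HSP90 genes, are uncertain.

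The table held 60623 genes, of which 33419 had no read in any library. IDs were paired with a gene name table (60295 paired) and with GENCODE 29 coordinates (58516 paired). Genes were kept by edgeR's filterByExpr with the 4 groups, which left 15010. Libraries were scaled by TMM, and a model with 1 mean per group was fitted to all 8 libraries with edgeR 4.0.16 (glmQLFit and glmQLFTest, 4 residual degrees of freedom, common dispersion 0.0288) in R 4.3.3. The 6 comparisons were contrasts of that fit, and p-values were adjusted by Benjamini-Hochberg within each comparison, with 0.05 as the threshold. The standard error was the fold change divided by the square root of the F statistic.

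The comparisons, the 37 gene lists, the panel of 30 genes, the filter, the tests and the alternatives were fixed before the data were examined, except a limma-voom fit with sample quality weights, which was added after the replicate spread had been seen. Lists with at least 5 tested members (36 of 37) were tested with limma 3.58.1 camera on log2 CPM (prior count 2) with a preset correlation of 0.01, and again with the correlation estimated from the data. No list passed with the estimated correlation in any comparison. In simulated data with independent genes that test called the 1 shifted list and 0 of the others. DESeq2 1.42.0, limma-trend on log2 TPM and fry were alternatives. Some genes belong to several lists, so results of lists that share members are not separate. Examples are SLC7A11 in the NRF2 and ATF4 lists, ACTA2 in the YAP/TEAD and TGF-beta lists, and FN1 in the matrix and epithelial-mesenchymal transition lists.

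Genes were named by a rule fixed in advance: the 8 largest fold changes in each direction in the 3 main comparisons, and 5 in the others, among genes with a symbol, an adjusted p under 0.05, a mean of at least 5 CPM over the 8 libraries and libraries that do not overlap between groups. Also named were up to 4 members with the smallest adjusted p of each list that was called or had at least 5 members passing, and the panel, whatever its result. A selection of the genes so named is printed. Some of them, panel genes included, are not reported here. KRT80 and IL13RA2, CDH1, TP63 and RLBP1, and the combination-against-control values of the genes moved back, were added after their values were seen. In groups with no read a floor of 3 reads over the group was used.

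Simulated data with 200 changed genes per comparison were analysed with the same code: 41% to 50% of genes changed 2-fold and 91% to 96% of those changed 4-fold were found in the 5 pairwise comparisons. False calls there ran from 10 of 145 calls (fucoidan against control) to 17 of 155 (combination against particulate). The simulation gave all groups the same spread, which the real replicates did not have, so these rates may not hold for each real comparison.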

Results

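Messenger RNA was measured in ARPE-19, an established line of human retinal pigment epithelium, the cell layer that nourishes the photoreceptors. Cells were kept for 24 h with the saline vehicle (control), with 400 µg/mL fucoidan, a sulfated polysaccharide of brown seaweed (fucoidan), with 200 µg/mL of a reference material of diesel exhaust particles that the labels call PM2.5 (particulate), or with both added at the same time (combination). Each of the 4 groups had 2 biological replicates, so the data held 8 libraries and every mean below has n = 2. Total counts ran from 12993565 in fucoidan replicate 1 to 17019284 in fucoidan replicate 2. Fold changes are log2 values with their standard error from edgeR's quasi-likelihood fit of all 8 libraries, and levels are normalised read counts (CPM) with the SD. Adjusted p-values are Benjamini-Hochberg values from the same fit. The particulate had been suspended in DMSO and no library received that solvent alone, so each comparison with particulate covers the particles together with their solvent.

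EEF1A1, a translation elongation factor, had the most counts in each library, with 1.23% to 1.70% of them. Mitochondrially encoded genes took 3.74% of the counts in particulate replicate 1 and 1.45% to 2.62% in the other 7 libraries. On the principal component with 62.6% of the variance, the 4 libraries without particulate lay between -53.4 and -39.2 and the 4 with it between 32.7 and 53.4. Combination replicate 1 stood apart on the component with 18.7% of the variance, at -58.4 against 8.62 for its replicate. Genes that differed at least 2-fold between the replicates made up 1.61% in control, 1.55% with fucoidan, 3.55% with particulate and 11.3% in the combination. Glycolysis and hypoxia genes were the clearest case: NDRG1, a hypoxia-induced gene, had 2579 CPM in combination replicate 1 and 115 CPM in replicate 2, and HK2, a hexokinase, had 672 and 52.1 CPM. All 29 tested genes of that list were higher in combination replicate 1. The particulate libraries differed on it too, with replicate 2 higher: NDRG1 had 222 and 769 CPM there and HK2 91.2 and 315 CPM.

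**Figure D1:**
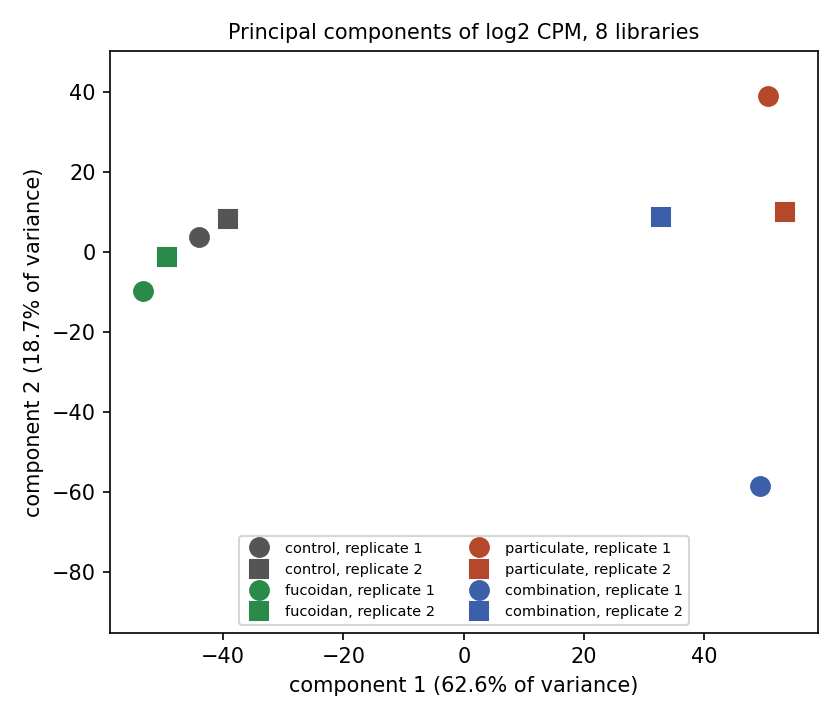
Scores of the 8 libraries on the first pair of principal components of log2 CPM, with the group given by colour and the replicate by marker. Libraries with particulate lie to the right of those without it, and combination replicate 1 lies lowest, at -58.4 on the component with 18.7% of the variance.

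The comparison of particulate with control asked what the particles, together with their solvent, did to expression without fucoidan. Antioxidant and glutathione genes rose, and genes of the extracellular matrix, the actin cytoskeleton and the tested part of a pigment epithelium list fell. SLC7A11, the cystine importer that feeds glutathione synthesis, went from 9.74 ± 0.0550 CPM in control to 131 ± 35.9 CPM with particulate (log2 fold change 3.75 ± 0.22, adjusted p = 1.83e-05). TGFB2, a transforming growth factor, went from 484 ± 2.28 to 50.7 ± 7.99 CPM (log2 fold change -3.25 ± 0.18, adjusted p = 1.72e-05). ELF3, an epithelial transcription factor on chromosome 1 at 202007945 to 202017188 (GRCh38), had 783 reads over the control libraries and none over the particulate libraries, which made it at least 295.5-fold lower against a floor of 3 reads over the group. Of 15010 genes tested, 3089 passed at an adjusted p under 0.05, with 1367 higher and 1722 lower, and 1637 of them changed at least 2-fold.

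Among genes with a mean of at least 5 CPM, the largest increases were those of ANGPTL4, a secreted inhibitor of lipoprotein lipase (0.610 ± 0.139 to 280 ± 146 CPM, log2 fold change 8.84 ± 1.16, adjusted p = 0.000876), and CHAC1, an enzyme that degrades glutathione (4.83 ± 0.62, adjusted p = 0.000782). CSF2, the granulocyte-macrophage colony-stimulating factor, rose by 4.61 ± 0.29 and MFSD2A, a lipid transporter, by 4.01 ± 0.38. PTX3, a secreted pattern-recognition protein, rose by 3.78 ± 0.46, and the chemokine gene CXCL3 by 3.68 ± 0.37. Large decreases besides that of ELF3 were those of its antisense gene ELF3-AS1 (at least 147-fold lower) and ANGPTL7, an angiopoietin-like secreted protein (log2 fold change -7.62 ± 0.29, adjusted p = 4.55e-06). The keratin gene KRT13 fell by 6.25 ± 0.44 on the log2 scale and the endothelin gene EDN2 by 5.98 ± 0.54. CRB2, a polarity gene, fell by 5.93 ± 0.29, and DIO2, which activates thyroid hormone, by 5.75 ± 0.63. For each of these genes the 2 libraries of one group lay outside the range of the other group, as the rule for naming them required. ELF3 and ELF3-AS1 overlap on opposite strands and the strand setting of the counting is not given in the sources used here, so their reads may not be separate. The same uncertainty holds for other genes named in this comparison that overlap a gene on the opposite strand: PTX3, ANGPTL7, CRB2, SQSTM1, DDIT3, IL6, ETV4, COL4A1, ACTA2, KIF20A, RDH10 and IFIT1.

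Of the 24 tested members of the NRF2 antioxidant and glutathione list, 17 rose (19 adjusted over the list alone) and none fell, with a median log2 fold change of 1.32 (camera adjusted p = 1.85e-10, adjusted p = 0.209 with an estimated correlation). NQO1, a quinone reductase, rose by 2.67 ± 0.18 (158 ± 17.8 to 1003 ± 87.6 CPM), and HMOX1, heme oxygenase, by 3.38 ± 0.49. GCLM, a subunit of the glutathione-synthesis enzyme, rose by 1.93 ± 0.19, TXNRD1, thioredoxin reductase, by 1.45 ± 0.14, and SQSTM1, an autophagy receptor, by 1.69 ± 0.16. The ferritin genes FTL and FTH1, which store iron, rose by 2.01 ± 0.16 and 1.71 ± 0.18, and have many pseudogenes that could take part of their reads. In the ATF4 amino acid response list, 14 of 28 members rose and 1 fell (18 and 1 adjusted over the list alone; median 0.90, camera adjusted p = 2.09e-05, adjusted p = 0.683 with an estimated correlation). Fry did not call the list (adjusted p = 0.101), and 18 of 25 rose in a fit of only the particulate and control libraries. PSAT1, a serine-synthesis enzyme, rose by 2.06 ± 0.25, and PCK2, a mitochondrial carboxykinase, by 1.10 ± 0.21 (adjusted p = 0.00663, 0.0874 and 0.0536 without control replicates 1 and 2). DDIT3, a stress transcription factor, rose by 1.39 ± 0.33 (adjusted p = 0.0161), but its adjusted p was 0.122 and 0.116 without control replicates 1 and 2, and 0.063 and 0.0659 without particulate replicates 1 and 2. In the heat shock list, 9 of 20 members rose and 2 fell (11 and 2 adjusted over the list alone; camera adjusted p = 0.0055, adjusted p = 0.354 with an estimated correlation). The chaperone genes HSP90AA1 and FKBP4 rose by 0.95 ± 0.15 and 0.96 ± 0.14, and the small heat shock protein genes CRYAB and HSPB1 fell by 1.37 ± 0.15 and 1.08 ± 0.18.

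In the list of inflammatory cytokines and NF-kB targets, 9 of 22 members rose and 1 fell (11 and 1 adjusted over the list alone), with a median of 1.10 (camera adjusted p = 0.00107, adjusted p = 0.209 with an estimated correlation). IL33, an epithelial alarmin, rose by 2.76 ± 0.44, and IL18, an inflammasome-dependent cytokine, fell by 1.55 ± 0.18. The chemokine gene CXCL8 rose by 2.90 ± 0.51 (adjusted p = 0.00418, 0.0677 without control replicate 1) and IL1B by 2.55 ± 0.57 (adjusted p = 0.013, 0.128 without control replicate 2 and 0.0956 without particulate replicate 1). IL6 (-0.10 ± 0.41, adjusted p = 0.88), CCL2 (-1.34 ± 0.66, adjusted p = 0.188) and ICAM1 (0.99 ± 0.42, adjusted p = 0.131) did not pass. In a fit of only the 4 particulate and control libraries CCL2 (adjusted p = 0.000216) and ICAM1 (adjusted p = 0.00173) passed and IL6 did not (adjusted p = 0.827), and 14 inflammatory genes rose and 2 fell. Among immediate early genes and feedback regulators of MAPK signalling, 12 of 29 rose and 2 fell (16 and 5 adjusted over the list alone; median 0.69, camera adjusted p = 0.00169, adjusted p = 0.675 with an estimated correlation). FOSL1, an AP-1 subunit, rose by 3.13 ± 0.24, and PHLDA1 by 2.46 ± 0.15. The ETS factor gene ETV4 rose too (adjusted p = 6.61e-05), whereas FOS, another AP-1 subunit, fell by 2.91 ± 0.24.

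Of the 21 fibrillar collagen and matrix genes, 15 fell (18 adjusted over the list alone) and none rose (median -1.29, camera adjusted p = 1.55e-08, adjusted p = 0.209 with an estimated correlation). COL1A1, a chain of type I collagen on chromosome 17 at 50183289 to 50201632, fell by 2.26 ± 0.18, COL5A2 by 1.91 ± 0.17, SPARC, a collagen-binding protein gene, by 1.73 ± 0.15, THBS1, thrombospondin, by 3.69 ± 0.36. FN1, fibronectin, fell as well (-1.65 ± 0.20). In the basement membrane list, 13 of 19 fell (14 fell and 2 rose adjusted over the list alone; camera adjusted p = 2.24e-05, adjusted p = 0.609 with an estimated correlation), among them COL4A1 (-2.17 ± 0.17) and HSPG2, perlecan (-1.92 ± 0.24). In the list of YAP/TEAD targets and actin cytoskeleton, 17 of 24 fell and 1, FOSL1, rose (20 and 1 adjusted over the list alone; camera adjusted p = 5.84e-08, adjusted p = 0.209 with an estimated correlation). ACTA2, smooth muscle actin, fell by 2.14 ± 0.17, TPM1, a tropomyosin gene, by 1.87 ± 0.15 and CNN2, a calponin gene, by 1.80 ± 0.15. Of the 25 TGF-beta and SMAD targets, 13 fell and 1 rose (14 and 1 adjusted over the list alone; median -0.78, camera adjusted p = 0.000168, adjusted p = 0.209 with an estimated correlation), with the inhibitor-of-differentiation genes ID2 and ID3 at -3.07 ± 0.27 and -3.29 ± 0.31. In the epithelial-mesenchymal transition list, 10 of 17 fell and none rose (12 fell and 1 rose adjusted over the list alone; camera adjusted p = 0.000345, adjusted p = 0.209 with an estimated correlation). That list held mesenchymal genes that fell, such as FN1, and epithelial ones that fell, such as CDH1, E-cadherin (-2.79 ± 0.59, adjusted p = 0.0103, 0.0576 and 0.0861 without control replicates 1 and 2, and from -5.01 to -1.89 over the 8 fits without 1 library). The keratin gene KRT19 fell too (-3.49 ± 0.63, adjusted p = 0.00479, 0.0511 without particulate replicate 1).

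In the retinal pigment epithelium identity list, 12 of 21 members fell and 1 rose (15 and 2 adjusted over the list alone; median -0.92, camera adjusted p = 7.96e-05, adjusted p = 0.209 with an estimated correlation). RDH10, a retinol dehydrogenase, fell by 2.74 ± 0.17, LRAT, which esterifies retinol, by 2.87 ± 0.30, and MITF, the pigment-cell transcription factor, by 1.84 ± 0.19. Other members, among them RPE65, RGR, TYR, TYRP1, DCT and MLANA, had too few reads to be tested (0 to 24 over all libraries). The list therefore covers only part of the pigment epithelium's genes. BEST1, a chloride channel gene, had a fold change of 2.40 ± 0.46 (adjusted p = 0.00628, 0.0759 without control replicate 2), but it overlaps FTH1 on the opposite strand and had 0.0102% to 0.0422% of FTH1's reads in the 8 libraries, so its value is uncertain. In the p53 target list, 12 of 24 fell and 2 rose (14 and 4 adjusted over the list alone; median -0.64, camera adjusted p = 0.00155, adjusted p = 0.213 with an estimated correlation). The antiproliferative gene BTG2 (-2.12 ± 0.17) and BBC3, the pro-apoptotic PUMA (-1.78 ± 0.19), were among those that fell. CDKN1A, the cell-cycle inhibitor p21, fell by 0.61 ± 0.19 (adjusted p = 0.0453), and its adjusted p was 0.0884 to 0.253 in the 6 fits that left out a control, fucoidan or particulate library. In the mitosis list, 11 of 29 fell and none rose (16 adjusted over the list alone; median -0.53, camera adjusted p = 1.41e-05, adjusted p = 0.609 with an estimated correlation), with KIF20A at -1.47 ± 0.17 and TOP2A at -1.13 ± 0.20. The mitotic kinase gene PLK1 fell by 0.69 ± 0.15 (adjusted p = 0.0102, 0.0948 and 0.0788 without control replicates 1 and 2). MKI67 (-0.77 ± 0.27, adjusted p = 0.0735) did not pass, but it did in the fit of only the particulate and control libraries (adjusted p = 0.00964), where 17 of 29 mitosis genes fell. In the cholesterol synthesis and uptake list, 6 of 23 fell and none rose (9 adjusted over the list alone; median -0.45, camera adjusted p = 0.00107, adjusted p = 0.663 with an estimated correlation). Its members HMGCS1 at -1.13 ± 0.17, INSIG1 at -1.15 ± 0.20 and SREBF2 at -0.96 ± 0.17 (adjusted p = 0.00373, 0.0526 without control replicate 1) were lower. In the fit of only the particulate and control libraries 11 of the 23 fell. LSS, lanosterol synthase, fell by 0.73 ± 0.14 (adjusted p = 0.00572, 0.0816 without control replicate 1).

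Mitochondrially encoded mRNAs were higher as a list (median 0.66, 2 of 13 rose, 3 adjusted over the list alone; camera adjusted p = 0.0055, adjusted p = 0.683 with an estimated correlation). That call was lost without control replicate 1 or particulate replicate 1, where the adjusted p reached 0.208, and particulate replicate 1 was the library with the 3.74% mitochondrial share. MT-CYB, a respiratory chain gene, rose by 1.03 ± 0.28 (adjusted p = 0.0284, 0.23 and 0.164 without those libraries). MT-ND4 rose by 0.94 ± 0.27 (adjusted p = 0.0366, 0.06 to 0.252 in the 4 fits without control replicate 1, particulate replicate 1 or either fucoidan library). Over the 8 fits without 1 library MT-CYB ran from 0.60 to 1.42 and MT-ND4 from 0.59 to 1.40, and fry did not call the list (adjusted p = 0.194). Camera did not call the other 21 lists. The counts over all genes were 4 rose and 2 fell of 16 for aryl hydrocarbon receptor and xenobiotic genes (5 and 2 adjusted over the list alone), 6 and 1 of 19 for iron handling (6 and 2), 2 and 1 of 8 for metallothioneins (3 and 1). They were 1 and 5 of 21 for interferon response (1 and 5), where the antiviral gene IFIT1 was at -2.09 ± 0.37 (adjusted p = 0.00434, 0.05 without particulate replicate 1). Counts were 2 and 0 of 15 for MHC class I (2 and 0), 6 and 6 of 20 for complement and coagulation (6 and 6) and 0 and 1 of 21 for the unfolded protein response (0 and 1). They were 4 and 1 of 23 for apoptosis regulators (7 and 3), 4 and 0 of 30 for DNA replication (4 and 0), 4 and 2 of 16 for fatty acid synthesis (4 and 2). Among LXR targets and metabolism lists they were 3 and 1 of 15 for LXR targets (4 and 1), 0 and 1 of 29 for glycolysis and hypoxia (0 and 0), 0 and 0 of 29 for nuclear oxidative phosphorylation genes (0 and 0) and 0 and 0 of 34 for ribosomal proteins (0 and 0). They were 8 and 2 of 34 for autophagy and lysosome (9 and 2), 3 and 6 of 19 for matrix metalloproteinases (3 and 7), 0 and 4 of 19 for tight and adherens junctions (0 and 5). The remaining lists had 4 and 8 of 21 for growth factors (7 and 8), 3 and 10 of 29 for heparan sulfate and glycosaminoglycan enzymes (4 and 11), 0 and 0 of 11 for scavenger and pattern receptors (0 and 0) and 5 and 6 of 21 for senescence secretory factors (6 and 7). Of the 27 genes of the list fixed for other cell types only 2 were expressed enough to be tested, TP63 (-5.02 ± 0.70) and RLBP1 (-2.34 ± 0.50, adjusted p = 0.0102, 0.0652 and 0.0692 without control replicates 1 and 2), and both fell. The fold change of RLBP1 ran from -3.99 to -1.60 over the 8 fits without 1 library. RLBP1 encodes a retinoid-binding protein that the pigment epithelium makes itself, so its fall belongs with the pigment epithelium genes. In the fit of only the particulate and control libraries other counts moved as well. Glycolysis and hypoxia genes had 9 higher and 8 lower of 29, DNA replication genes 8 and 1 of 30 and apoptosis regulators 7 and 3 of 23. Unfolded protein response genes had 2 and 2 of 21, LXR targets 5 and 2 of 14 and growth factors 9 and 9 of 20. The mean level of the glycolysis and hypoxia list was 7.08 and 7.84 in particulate replicates 1 and 2. These lay on either side of the control libraries, at 7.51 and 7.44.

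Of the 30 genes of a panel fixed in advance, 27 were tested, and 12 rose and 5 fell with particulate. TIPARP, a target of the aryl hydrocarbon receptor, rose by 1.15 ± 0.15, while the receptor's targets CYP1A1 (1.88 ± 0.76, adjusted p = 0.11) and CYP1B1 (1.13 ± 0.74, adjusted p = 0.313) did not pass. In the fit of only the particulate and control libraries both passed (adjusted p = 0.000192 and 0.0038), and 7 of the 16 genes of the receptor's list rose and 2 fell. That list also holds NQO1 of the NRF2 list and SLC7A5 and STC2 of the ATF4 list, so its members are not specific to the receptor. MT2A, a metallothionein gene, rose by 1.28 ± 0.20. MMP1, collagenase, had 1 read in control and 112 with particulate, a ratio of 98.9 with a counting interval of 17.4 to 3942 (adjusted p = 0.00483, 0.0734 and 0.0511 without control replicates 1 and 2). TJP1, a tight junction scaffold, fell by 0.66 ± 0.20 (adjusted p = 0.0401, 0.0753 to 0.217 without either control library, either fucoidan library or particulate replicate 1, and -0.98 to -0.36 over the 8 fits). VEGFA (0.93 ± 0.61, adjusted p = 0.319) and HSPA5 (-0.20 ± 0.14, adjusted p = 0.349) did not pass, though VEGFA did in that smaller fit (adjusted p = 0.0327). VEGFA had 217 and 175 CPM in control and 211 and 535 CPM in particulate replicates 1 and 2. Particulate replicate 1 thus lay within the control range. The fit of only the particulate and control libraries called 4187 genes, 1950 higher and 2237 lower. AHRR, PTGS2 and RPE65 had 0 to 3 reads per library and were not tested. The count of 3089 depended on which libraries were in the fit: it was 906 and 1198 without control replicates 1 and 2, 2032 and 2045 without fucoidan replicates 1 and 2, and 1862 without particulate replicate 1. It was 5000 and 5003 without combination replicates 1 and 2, and 2006 with limma-trend on the deposited TPM.

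**Figure D2:**
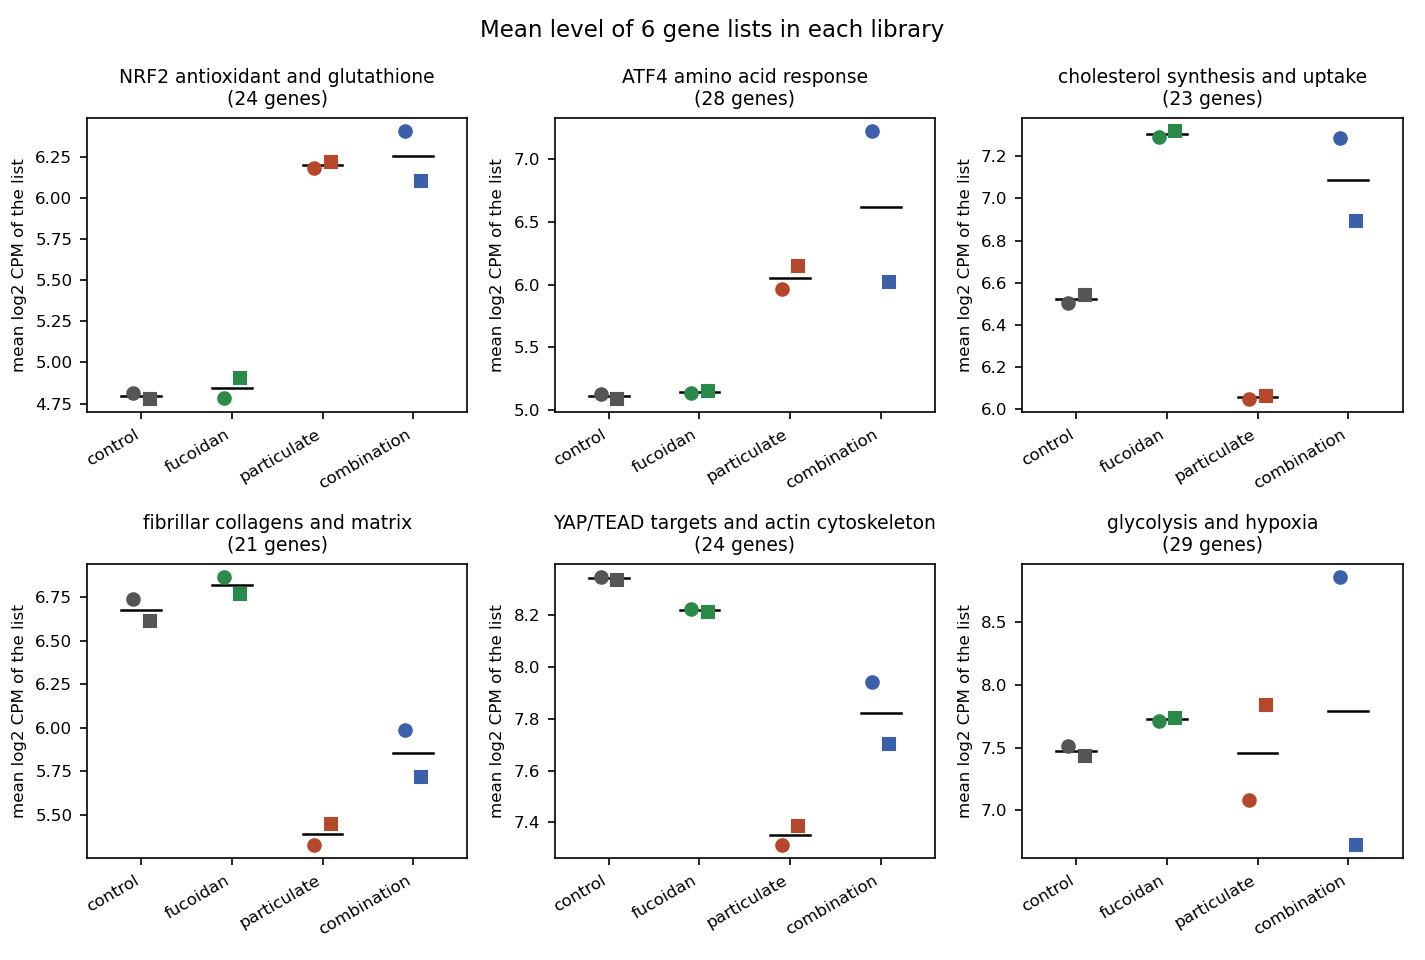
Mean log2 CPM of 6 gene lists in each library, with circles for replicate 1, squares for replicate 2 and a line for the group mean. The cholesterol list lies higher in both fucoidan libraries than in both control libraries and higher in both combination libraries than in both particulate libraries, and the glycolysis and hypoxia list differs by 2.14 between the combination libraries.

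The comparison of fucoidan with control asked what fucoidan did without particles. Genes of cholesterol synthesis were higher as a group in fucoidan, and no gene passed the test alone. HMGCS1, which makes the precursor of mevalonate (chromosome 5, 43289395 to 43313512), had 173 ± 17.8 CPM in control and 466 ± 8.70 CPM with fucoidan (log2 fold change 1.43 ± 0.17, adjusted p = 0.0953). COL1A1 had 67.9 ± 12.6 and 185 ± 23.2 CPM (1.44 ± 0.17, adjusted p = 0.0953). Of the 23 cholesterol synthesis and uptake genes, 22 had a positive fold change, the median was 0.77 and camera called the list (adjusted p = 4.97e-27, adjusted p = 0.555 with an estimated correlation). None of its members passed over all genes, and 20 were higher when adjusted over the list alone.

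Among the members, IDI1 (0.97 ± 0.15), ACAT2 (0.90 ± 0.16) and MVD (1.22 ± 0.21) had adjusted p between 0.245 and 0.298. The fatty acid synthesis list was also higher (median 0.27, 0 of 16 passed and 4 adjusted over the list alone; camera adjusted p = 6.55e-06, adjusted p = 0.665 with an estimated correlation). Its members included PNPLA3 at 1.10 ± 0.23, ACSS2 at 0.69 ± 0.15 and the desaturase gene FADS2 at 0.60 ± 0.16. ACAT2 and ACSS2 overlap other genes on the opposite strand, and PNPLA3 and FADS2 on the same strand, so their values are uncertain. The DNA replication list was lower, with all 30 members negative (median -0.29, 0 passed and 1 adjusted over the list alone). The camera adjusted p was 4.75e-06, and 0.818 with an estimated correlation. Fry did not call the list (adjusted p = 0.778). Examples were E2F1 (-0.81 ± 0.18) and MCM3 (-0.36 ± 0.18). Its mean level was 5.798 and 5.987 in the control libraries and 5.475 and 5.696 with fucoidan. The replicates of each group thus differed by more than the gap between the groups. Heat shock genes were lower (camera adjusted p = 0.0163, adjusted p = 0.665 with an estimated correlation), for example FKBP4 (-0.52 ± 0.14) and HSPH1 (-0.56 ± 0.17). That call was lost without control replicate 2 or fucoidan replicate 1 (highest adjusted p = 0.152). Unfolded protein response genes were higher (camera adjusted p = 0.0431, adjusted p = 0.818 with an estimated correlation), for example HSPA5, a chaperone of the endoplasmic reticulum (0.44 ± 0.14), and MANF (0.38 ± 0.22). The call was lost without control replicate 1 or either fucoidan library (highest adjusted p = 0.203). Mitochondrially encoded mRNAs were lower (median -0.33, camera adjusted p = 0.0437, adjusted p = 0.931 with an estimated correlation), a call lost in 5 of the 8 fits without 1 library and turned without control replicate 2 (adjusted p up to 0.995). The mitochondrial share of counts was 2.27% in control replicate 2 and 1.45% to 1.52% in the other 3 libraries compared. No member of these lists passed over all genes or, for the last 3 lists, adjusted over the list alone. In a fit of only the 4 fucoidan and control libraries 4 heat shock genes fell, 3 unfolded protein response genes rose and 3 mitochondrial mRNAs fell. FKBP4 (adjusted p = 0.000747), HSPH1 (0.00034), HSPA5 (0.00859) and MANF (0.022) passed in it.

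With edgeR, 0 genes passed in fucoidan against control, 662 genes (4.4% of those tested) had an unadjusted p under 0.05, and DESeq2 called 23, with 20 higher and 3 lower. The fit shared its spread with the particulate and combination libraries, whose replicates differed more: the SD of the log2 difference between replicates was 0.317 in control, 0.31 with fucoidan, 0.451 with particulate and 0.663 in the combination. A fit of only the 4 fucoidan and control libraries called 849 genes, with 474 higher and 375 lower, and among them were 20 of the 23 cholesterol genes and 8 of the 16 fatty acid genes, all higher, and 7 of the 30 DNA replication genes, all lower. The count was 38 without combination replicate 1, 32 without combination replicate 2, 73 with no low-count filter and 313 with sample quality weights. None of the 27 panel genes passed in the fit of all libraries, while HMGCS1 (adjusted p = 1.22e-12), COL1A1 (2.99e-12) and HSPA5 (0.00859) passed in the fit of only fucoidan and control. Other lists moved in that smaller fit too. YAP/TEAD targets and actin genes had 0 higher and 6 lower of 24, glycolysis and hypoxia genes 7 and 0 of 29, and immediate early genes 4 and 7 of 29. No gene could be called with both fucoidan and particulate, because none was called with fucoidan. The fold changes of these 2 comparisons, which share the control libraries, correlated at -0.082 across genes, against 0.51 in simulations of unchanged groups. The covariance was -0.0258 against 0.0316. Particulate did change many genes, which the simulation left out, so the 2 correlations cannot be compared directly.

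**Figure D3:**
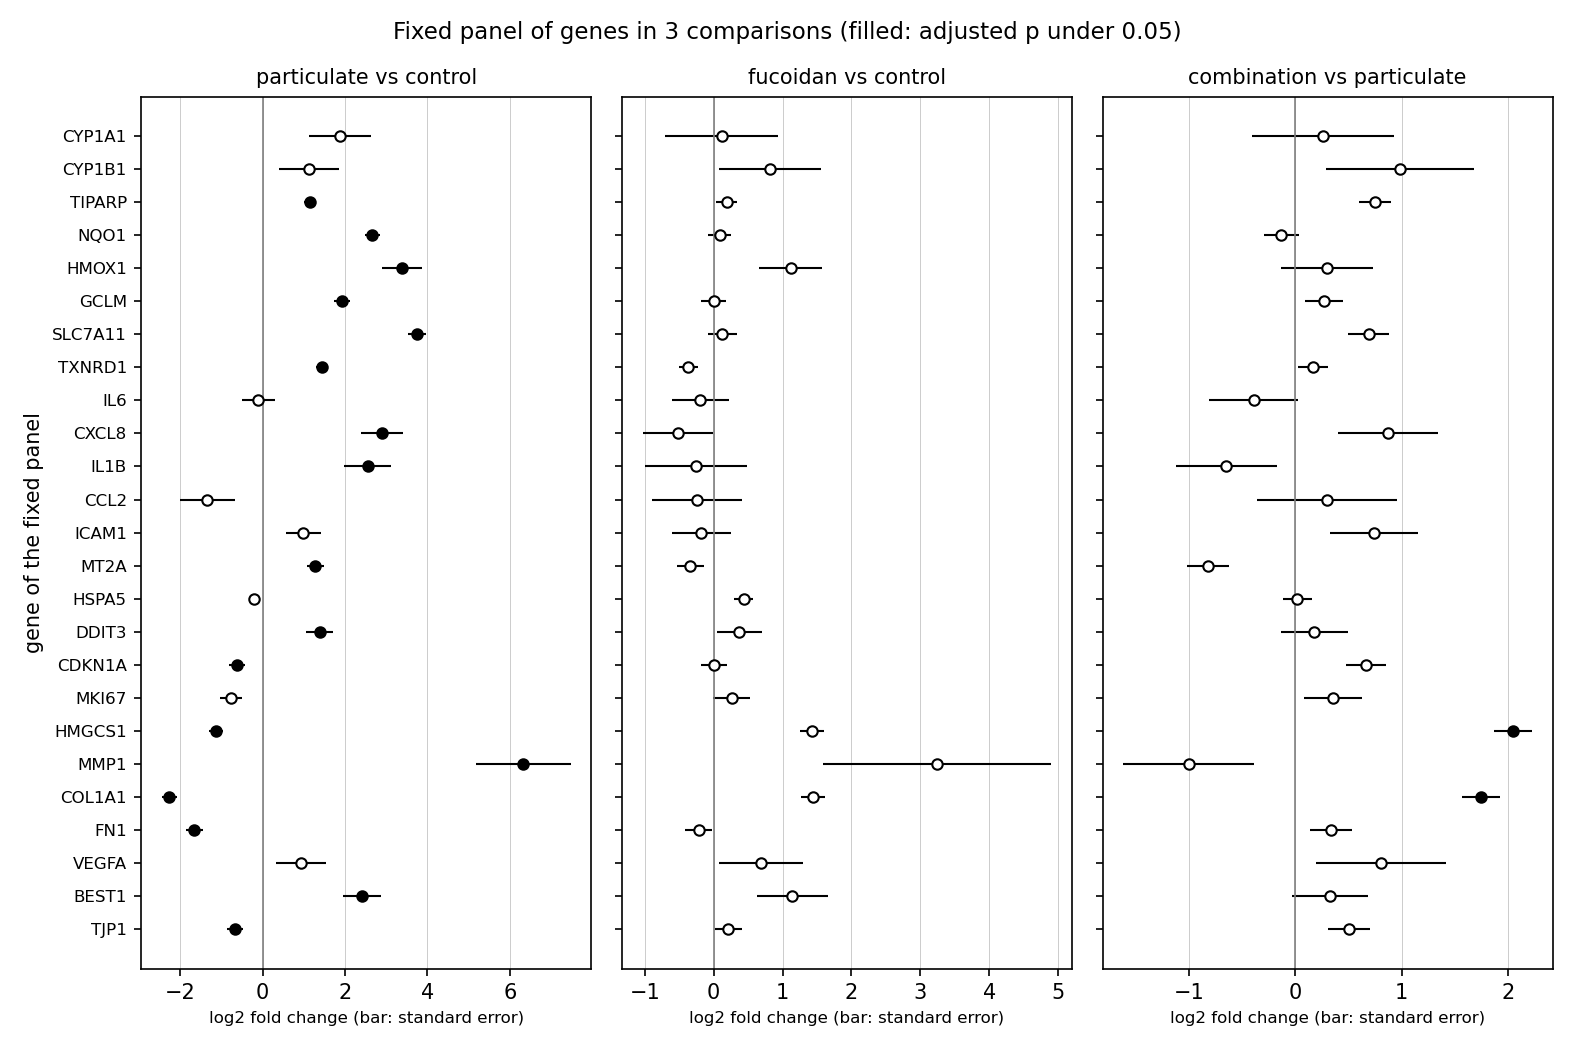
Log2 fold changes of the tested panel genes named in the text (points) with standard errors (bars) in 3 comparisons, with filled points for an adjusted p under 0.05; the horizontal scales differ between the comparisons. With particulate 12 genes rose and 5 fell, with fucoidan none passed, and in the combination against particulate HMGCS1 and COL1A1 rose.

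The comparison of the combination with particulate asked what fucoidan changed in cells that also received particles. Few genes passed, and they were mainly genes of cholesterol synthesis and genes that particulate had lowered. HMGCS1 rose from 79.1 ± 8.03 CPM with particulate to 328 ± 63.5 CPM in the combination (log2 fold change 2.05 ± 0.18, adjusted p = 0.00967). INSIG1, a sterol-regulated gene (chromosome 7, 155297776 to 155310235), rose from 62.5 ± 7.43 to 222 ± 66.9 CPM (1.83 ± 0.21, adjusted p = 0.0249). COL1A1 rose by 1.75 ± 0.18 (adjusted p = 0.021) and reached 47.5 ± 2.03 CPM, and TGFB2 rose by 1.33 ± 0.17 (adjusted p = 0.0255). These values share the spread of all groups, and the control and fucoidan replicates differed less than those compared here. In a fit of only the combination and particulate libraries none of the genes just named passed (adjusted p from 0.303 for HMGCS1 to 0.518 for TGFB2). EdgeR called 13 of 15010 genes, 12 higher and 1 lower, 2599 had an unadjusted p under 0.05, and DESeq2 called 306, with 260 higher and 46 lower.

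The other genes that rose were MSMO1 (1.94 ± 0.24) and IDI1 (1.23 ± 0.15) of cholesterol synthesis, MYOCD, a coactivator of smooth muscle genes (1.99 ± 0.23), and PIK3IP1, an inhibitor of phosphoinositide 3-kinase (1.94 ± 0.27). NEDD9, a focal adhesion scaffold (1.71 ± 0.22), the cell-cycle inhibitor gene CDKN2B (1.37 ± 0.17), KRT80 (1.17 ± 0.14) and a gene with no symbol in the sources used rose as well. IL13RA2, a decoy receptor for interleukin 13, fell by 1.66 ± 0.23. KRT80 and IL13RA2 were named after their values were seen. In the cholesterol list 4 of 23 members rose (20 adjusted over the list alone), the median was 0.95, and the camera adjusted p was 2.28e-17 (adjusted p = 0.458 with an estimated correlation). Fatty acid synthesis genes were higher as a list (0 of 16 passed, 5 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.00143, adjusted p = 0.458 with an estimated correlation), with PNPLA3 at 1.63 ± 0.24 and FADS2 at 0.78 ± 0.16. YAP/TEAD targets and actin genes were higher (median 0.44, 0 of 24 passed, 9 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.000334, adjusted p = 0.458 with an estimated correlation), with AMOTL2 at 1.11 ± 0.18 and ANKRD1 at 2.65 ± 0.49. Fibrillar collagens were higher (median 0.43, 1 of 21 rose and 6 adjusted over the list alone; camera adjusted p = 0.000255, adjusted p = 0.458 with an estimated correlation), with COL5A1 at 1.04 ± 0.24. Nuclear oxidative phosphorylation genes were lower, all 29 of them negative (median -0.26, 0 passed either way), for example NDUFA8 (-0.59 ± 0.17). The camera adjusted p was 7.65e-05, and 0.602 with an estimated correlation. Their mean level was 6.359 and 6.081 in particulate replicates 1 and 2, and 5.927 and 5.941 in the combination libraries. The particulate replicates thus differed by more than the gap to the combination. These 5 lists were called in each of the 8 fits without 1 library. After correction for GC content and transcript length all 5 were still called, but the median of the fibrillar collagens fell from 0.44 to 0.23 (adjusted p = 0.0012).

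Another 9 lists were called with calls that 1 library could end. ATF4 response genes were higher (median 0.55, all 28 positive, 0 passed either way; camera adjusted p = 0.000255, adjusted p = 0.709 with an estimated correlation), for example ATF3 (1.58 ± 0.41) and SLC7A11 (0.69 ± 0.19), but without combination replicate 1 the direction turned (adjusted p = 0.53). DNA replication genes were lower (camera adjusted p = 1.36e-05, adjusted p = 0.654 with an estimated correlation; 0.327 without combination replicate 1), for example CDT1 (-0.56 ± 0.19). The p53 targets were higher (9 adjusted over the list alone and 0 over all genes; camera adjusted p = 0.00202, adjusted p = 0.458 with an estimated correlation; 0.0682 without combination replicate 2), with BTG2 at 0.93 ± 0.17 and BBC3 at 0.89 ± 0.19. Heat shock genes were lower (0 of 20 passed and 1 adjusted over the list alone; camera adjusted p = 0.00316, adjusted p = 0.458 with an estimated correlation; 0.0535 without combination replicate 2), with FKBP4 at -0.60 ± 0.14. Mitosis genes were higher (camera adjusted p = 0.034, adjusted p = 0.765 with an estimated correlation), lost without particulate replicate 2 or combination replicate 2, where it turned (up to 0.882). Ribosomal protein genes were lower (camera adjusted p = 0.0355, adjusted p = 0.894 with an estimated correlation), lost and turned without particulate replicate 1 or combination replicate 2 (up to 0.903). Basement membrane genes were higher (0 of 19 passed and 2 adjusted over the list alone; camera adjusted p = 0.024, adjusted p = 0.719 with an estimated correlation), with COL4A1 at 0.80 ± 0.17, lost without particulate replicate 1 or either combination library (up to 0.271). TGF-beta targets were higher (1 of 25 rose, 6 higher and 2 lower adjusted over the list alone; camera adjusted p = 0.0413, adjusted p = 0.458 with an estimated correlation), lost without control replicate 1, either particulate library or combination replicate 1 (up to 0.327). Glycosaminoglycan enzyme genes were higher (camera adjusted p = 0.0331, adjusted p = 0.654 with an estimated correlation), lost without particulate replicate 1 or combination replicate 1 (up to 0.327). Correction for GC content and transcript length ended 3 of these 9 calls, those of ribosomal proteins (adjusted p = 0.419), basement membrane (0.206, median 0.09) and glycosaminoglycan enzymes (0.132).

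Whether fucoidan changed the antioxidant response to particles was left open by the spread of the combination libraries. NQO1 had a fold change of -0.13 ± 0.17 (adjusted p = 0.689) in the combination against particulate, HMOX1 0.30 ± 0.44 (adjusted p = 0.735) and CXCL8 0.87 ± 0.47 (adjusted p = 0.349). The signs of all 3 rested on 1 library. Without combination replicate 1, HMOX1 was at -0.93 (adjusted p = 0.0322) and CXCL8 at -0.20 (adjusted p = 0.792). Without combination replicate 2, HMOX1 was at 0.95 (adjusted p = 0.00172), CXCL8 at 1.48 (adjusted p = 0.00756) and NQO1 at 0.00, so HMOX1 passed in opposite directions. Of the NRF2 list, 0 of 24 members passed (0 adjusted over the list alone), and camera gave an adjusted p of 0.913. The count of 13 was 0 without control replicate 1 or 2, fucoidan replicate 1 or particulate replicate 2, 1 without fucoidan replicate 2 or particulate replicate 1, 59 without combination replicate 1, 3257 without combination replicate 2, and 0 in a fit of only the 4 libraries compared, where 0 of 23 cholesterol genes rose and HMGCS1 had an adjusted p of 0.303. HMGCS1 lost its call in 5 of the 8 fits without 1 library (adjusted p from 0.0504 to 0.216 there). The other named genes lost theirs in 6 of 8, those that left out a control, fucoidan or particulate library (adjusted p from 0.0604 to 0.574), while each kept its direction in all 8.

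Genes that particulate had changed and that the combination moved back were counted next. Of the 3089 genes called with particulate, 11 were called in the opposite direction in the combination against particulate, 10 of them lower and then higher and 1, IL13RA2, higher and then lower, and none was called in the same direction. Independent calls would give 1.4 and 0.1. Some of these genes were also higher with fucoidan alone. HMGCS1 had 460 and 472 CPM there against 161 and 186 CPM in control, and INSIG1 294 and 300 against 137 and 141 CPM. COL1A1 was higher too (1.455 ± 0.113 with only the fucoidan and control libraries). The others are not given here. The count therefore does not tell an offset of the particle response apart from an effect that fucoidan also had without particles. The comparisons of particulate with control and of the combination with particulate both use the particulate libraries, which alone pull their fold changes apart. Across genes, which are not independent replicates, the correlation was -0.427, against -0.491 in 50 simulations of unchanged groups that share those libraries. The covariance was -0.206 against -0.0753, and the simulations gave 0 shared calls. They left out the particulate effect and the wider spread of the combination replicates, so these values cannot be compared directly. Relative to control, HMGCS1 (0.92 ± 0.17) and INSIG1 (0.67, adjusted p = 0.0477, but 0.0558 to 0.252 in 6 of the 8 fits without 1 library and 0.112 with only the combination and control libraries) ended above the control level. INSIG1 was at 0.34 without combination replicate 1 and 0.95 without replicate 2. COL1A1 (-0.51 ± 0.17, adjusted p = 0.0672) and NEDD9 (-0.18, adjusted p = 0.575, at 0.11 without combination replicate 2) did not pass. TGFB2 (-1.92), PIK3IP1 (-1.32, adjusted p = 0.00832, 0.0806 and 0.0589 without control replicates 1 and 2, 0.0559 with only those libraries), MYOCD (-1.74), CDKN2B (-1.55), KRT80 (-1.50) and the gene with no symbol (-1.10, adjusted p = 0.00644) stayed lower. IL13RA2 stayed above control (1.42, adjusted p = 0.00738, 0.051 and 0.0908 without control replicates 1 and 2, 0.0536 with only those libraries). The count of 11 was 0 or 1 without any control, fucoidan or particulate library, 53 without combination replicate 1 and 1066 without combination replicate 2.

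**Figure D4:**
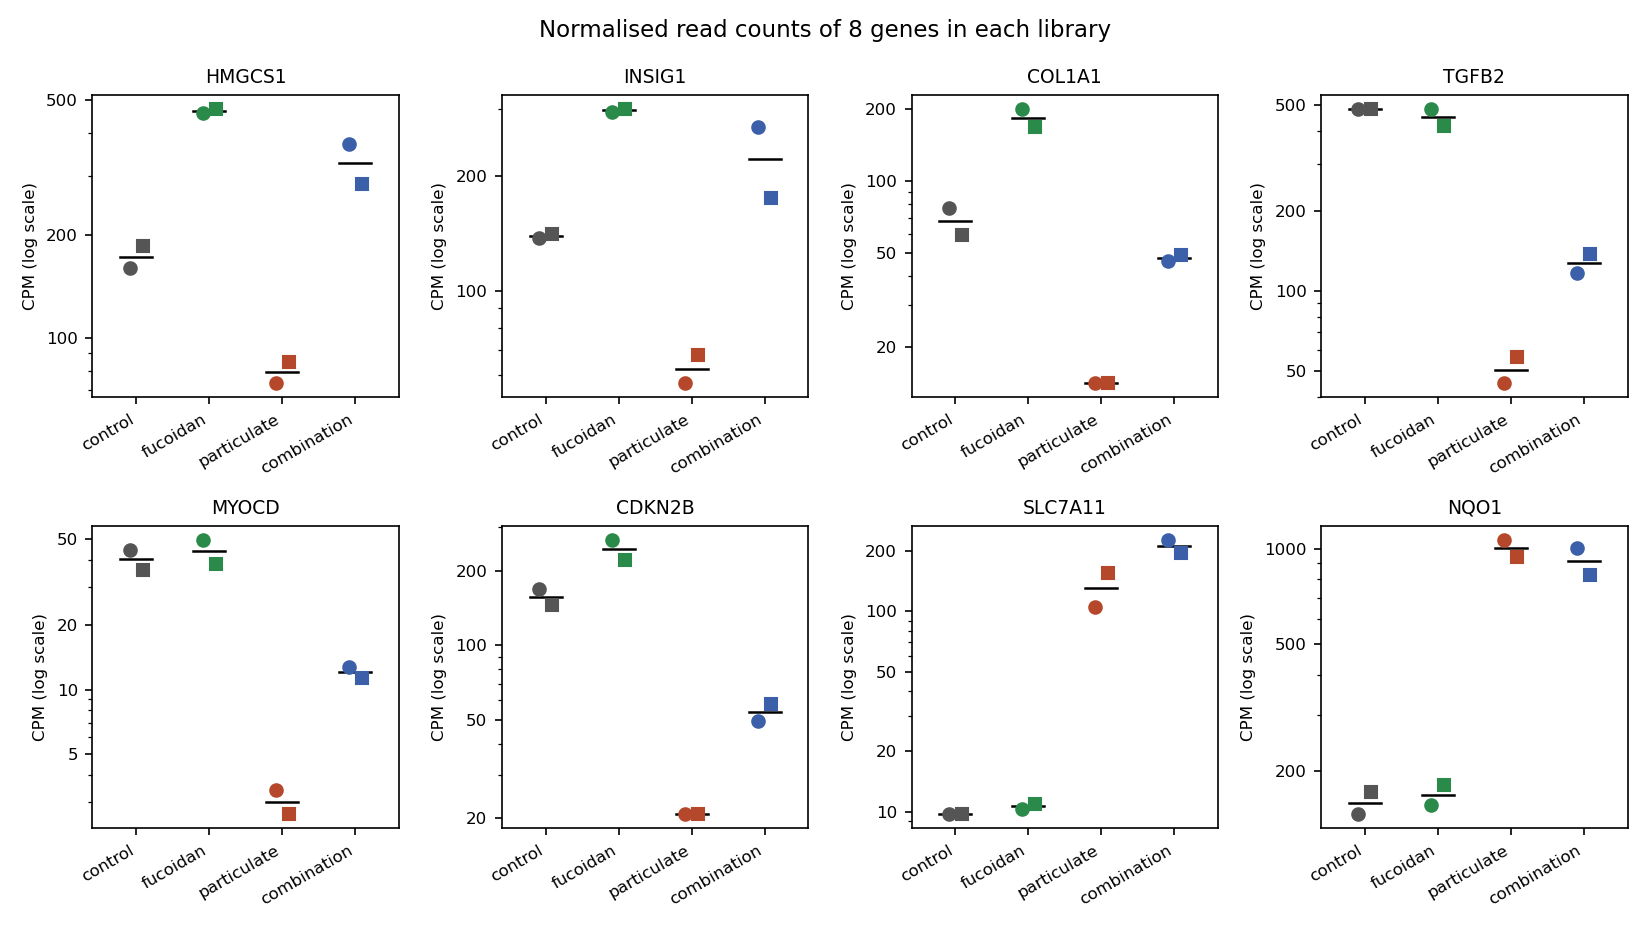
Normalised read counts (CPM, log scale) of 8 genes in each library, with circles for replicate 1, squares for replicate 2 and a line for the group mean. HMGCS1, INSIG1, COL1A1, TGFB2, MYOCD and CDKN2B were lower with particulate than in control and higher in the combination than with particulate. HMGCS1, INSIG1 and COL1A1 were also higher with fucoidan alone than in control. SLC7A11 and NQO1 stayed high in both groups with particulate.

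The combination against control gives the joint change. Antioxidant and ATF4 genes rose and matrix genes fell, while cholesterol synthesis genes, which particulate alone had lowered, were higher. SLC7A11 rose from 9.74 ± 0.0550 to 211 ± 22.8 CPM (log2 fold change 4.44 ± 0.23, adjusted p = 1.99e-05) and NQO1 by 2.53 ± 0.18 (SE 0.175). ANGPTL4 (8.85 ± 1.16), CHAC1 (5.36 ± 0.62), CSF2 (4.22 ± 0.29) and the interleukin 6 receptor gene IL6R (4.81 ± 0.72, adjusted p = 0.00282, 0.0504 without control replicate 1) were among the largest increases. Among the largest decreases were ELF3 (-6.91 ± 0.34), KRT13 (-5.94 ± 0.43), ELF3-AS1 (-5.72 ± 0.43), EDN2 (-5.64 ± 0.52) and ANGPTL7 (-5.32 ± 0.23). EdgeR called 2556 genes, 1226 higher and 1330 lower, of which 1386 changed at least 2-fold.

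Cholesterol genes were higher in the combination than in control (11 of 23 rose and 14 adjusted over the list alone; median 0.56, camera adjusted p = 0.000105, adjusted p = 0.459 with an estimated correlation). IDI1 rose by 1.10 ± 0.15 (adjusted p = 0.00191, 0.0503 without control replicate 1). MSMO1 (1.29 ± 0.23), HMGCS1 (0.92 ± 0.17) and SC5D (1.04 ± 0.21) rose too, and each lost the call without control replicate 1 (0.0939 to 0.127) and without control replicate 2 (0.0567 to 0.0971). In a fit of only the 4 combination and control libraries 2 of the 23 cholesterol genes rose, and MSMO1 (adjusted p = 0.0502) and SC5D (adjusted p = 0.0527) did not pass. MSMO1 ran from 0.83 to 1.64 and SC5D from 0.70 to 1.33 over the 8 fits without 1 library. In the NRF2 list 17 of 24 rose (19 rose and 1 fell adjusted over the list alone; camera adjusted p = 7.69e-11, adjusted p = 0.342 with an estimated correlation). In the ATF4 list 22 of 28 rose (24 and 1; camera adjusted p = 1.1e-09, adjusted p = 0.459 with an estimated correlation), among them PSAT1 (2.81 ± 0.26). Inflammatory genes rose, 13 of 22 with 2 falling (15 and 3 adjusted over the list alone; camera adjusted p = 0.000509, adjusted p = 0.342 with an estimated correlation), among them CXCL8 (3.78 ± 0.53). With only the combination and control libraries, 9 of 28 ATF4 genes rose, and 8 inflammatory genes rose and 1 fell. The ATF4 list had a mean level of 7.23 in combination replicate 1 and 6.02 in replicate 2. Fibrillar collagens fell, 9 of 21 (12 adjusted over the list alone; camera adjusted p = 1.91e-05, adjusted p = 0.342 with an estimated correlation). YAP/TEAD targets fell as well, 11 of 24 with 1 rising (14 and 2; camera adjusted p = 0.000509, adjusted p = 0.342 with an estimated correlation). Camera called 18 lists in all, and none with an estimated correlation. Of these, 7 were lost without a combination library. Without combination replicate 1 or another library, the highest adjusted p was 0.257 for interferon response, 0.0903 for mitosis, 0.271 for mitochondrial mRNA and 0.479 for autophagy. Without combination replicate 2 it was 0.425 for ribosomal proteins, 0.177 for TGF-beta targets and 0.0729 for epithelial-mesenchymal transition. The ribosomal protein call was also lost after correction for GC content and transcript length (adjusted p = 0.0703). The count of 2556 was 407 and 588 without control replicates 1 and 2, 1466 and 1469 without fucoidan replicates 1 and 2, 5137 without combination replicate 2, 1480 with limma-trend on TPM and 1026 in a fit of only the 4 libraries compared.

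The combination against fucoidan shows the effect of particles, together with their solvent, in cells that had fucoidan. The response resembled that of particulate alone: of the 3089 and 3110 genes called, 2009 were called in both comparisons and all 2009 had the same direction, 872 higher and 1137 lower, where independent calls would give 139 and 182. These comparisons share no library, and their fold changes correlated at 0.815 across genes. SLC7A11 rose by 4.31 ± 0.22 (adjusted p = 1.97e-05), NQO1 by 2.45 ± 0.17, FOSL1 by 3.72 ± 0.25 and SPRY4, a feedback inhibitor of MAPK signalling, by 4.99 ± 0.54. ANGPTL4 (7.88 ± 1.08), CHAC1 (5.01 ± 0.60) and IL6R (4.42 ± 0.69) also rose. ELF3 (-6.79 ± 0.34), EDN2 (-6.39 ± 0.51), ANGPTL7 (-6.36 ± 0.24), KRT13 (-6.07 ± 0.43), ELF3-AS1 (-5.92 ± 0.43) and COL1A1 (-1.96 ± 0.18) fell.

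HMGCS1 was at -0.51 ± 0.17 (adjusted p = 0.0619) and the cholesterol list was not called (0 rose and 3 fell of 23, 0 and 2 adjusted over the list alone; camera adjusted p = 0.0755). HSPA5 fell by 0.61 ± 0.14 (adjusted p = 0.0146, 0.109 and 0.104 without fucoidan replicates 1 and 2). EdgeR called 3110 genes, 1526 higher and 1584 lower, of which 1666 changed at least 2-fold, and camera called 16 lists, none with an estimated correlation (smallest adjusted p = 0.391 with an estimated correlation). The NRF2 (16 of 24 rose, 19 adjusted over the list alone), ATF4 (23 rose and 1 fell of 28, 24 and 1 adjusted over the list alone), matrix (12 of 21 fell, 12 adjusted over the list alone) and basement membrane lists (10 of 19 fell, 13 adjusted over the list alone) were among them in each of the 8 fits without 1 library. The YAP/TEAD and TGF-beta lists, both lower, were not called without combination replicate 2 (adjusted p = 0.0951 for each), nor were mitochondrial mRNAs (0.0589). The interferon, heat shock, p53, mitosis, ribosomal protein and epithelial-mesenchymal transition calls were lost in 2 to 6 of the 8 fits, with adjusted p up to 0.193, 0.146, 0.127, 0.242, 0.644 and 0.147. After correction for GC content and transcript length the ribosomal protein call was lost (adjusted p = 0.178) and the interferon median went from -0.50 to -0.23. The count of 3110 was 1899 and 1894 without control replicates 1 and 2, 743 and 901 without fucoidan replicates 1 and 2, 5339 without combination replicate 2, 1993 with limma-trend on TPM and 1511 in a fit of only the 4 libraries compared. In that fit 12 of 27 ATF4 genes rose and 1 fell, 9 of 20 matrix genes fell, and HSPA5 did not pass (adjusted p = 0.0527).

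The interaction asked whether fucoidan changed expression by a different amount with and without particles. YAP/TEAD targets and actin genes differed most clearly as a list. Fucoidan shifted them by a median of -0.05 without particles and 0.44 with them. In the fit of only the fucoidan and control libraries 6 of 24 members fell and 0 rose. With only the combination and particulate libraries 0 of 23 rose and 0 fell. The median interaction was 0.48, with 22 of 24 members positive (camera adjusted p = 6.94e-07, adjusted p = 0.49 with an estimated correlation). Adjusted over the list alone, 4 members were higher. AMOTL2 had an interaction of 1.16 ± 0.25, ANKRD1, a cardiac ankyrin repeat gene, 2.66 ± 0.67, AJUBA 0.79 ± 0.21 and CRIM1 1.02 ± 0.28, with adjusted p between 0.642 and 0.897. No single gene passed with edgeR, 668 had an unadjusted p under 0.05, and DESeq2 called 20. On simulated data the interaction test found 9% of genes changed 2-fold and 68% of those changed 4-fold. The count was 2 without combination replicate 1 and 865 without combination replicate 2. Between the comparisons of fucoidan with control and combination with particulate, which share no library, the fold changes correlated at 0.26 across genes.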

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

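The GC and length test below was chosen before its result was seen, and the level tests of combination replicate 1 were chosen after the spread had been seen. Glycolysis and hypoxia genes differed between the combination libraries by a median of 2.12, and by 2.09 after GC content and transcript length were corrected for. The particulate libraries differed in the other direction, with mean levels of 7.08 and 7.84. A lack of fucoidan in combination replicate 1 did not explain it, as its cholesterol list lay 1.22 above the higher particulate library, and a lack of particles did not either, as its NRF2 list lay 1.5 above the highest library without them. No biological cause of the difference, such as oxygen supply or cell density, was tested.

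8 gene lists differed in the effect of fucoidan with and without particles (camera with the preset correlation; none passed with an estimated correlation). The median interaction of the ATF4 list was 0.618, and the call was lost and turned without combination replicate 1 (adjusted p = 0.893). The p53 targets had 0.229, lost in 5 of the 8 fits without 1 library (adjusted p up to 0.251), and 0.12 after correction for GC content and transcript length. Mitosis genes had 0.18, lost in 3 fits (up to 0.968). Nuclear oxidative phosphorylation genes had -0.234, lost in 3 fits (up to 0.101). Fibrillar collagens had 0.305, lost in 4 fits (up to 0.269) and after the same correction (adjusted p = 0.104). The epithelial-mesenchymal transition list had 0.255, lost in 5 fits (up to 0.195). Glycosaminoglycan enzyme genes had 0.217, lost in 4 fits (up to 0.107). YAP/TEAD targets and actin genes had 0.476, the only one of the 8 called in each fit without 1 library (adjusted p up to 7.93e-05).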

How the results depend on the processing

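For 169 gene and comparison pairs printed, 2026 alternative values were computed: 1805 were the same, 154 weaker, 62 stronger and 5 reversed. A value was the same if it kept its sign and its side of the threshold, so a pair that stayed uncalled also counted as the same. Weaker values lost the call and stronger ones gained it. Of 124 called pairs, 86 kept the call in each fit without 1 library. The reversed ones were IL6 with particulate (-0.458 to 0.224 over the 8 fits without 1 library), NQO1 (-0.283 to 0.002), HMOX1 (-0.925 to 0.948) and CXCL8 (-0.198 to 1.477) in the combination against particulate, and NEDD9 in the combination against control (-0.549 to 0.114).

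Genes changed with particulate against control numbered 2006 with limma-trend on TPM, and 906 to 5003 without 1 library. In fucoidan against control they were 73 with no filter, 23 with DESeq2, 313 with limma-voom and sample quality weights, 849 with only the libraries of the groups compared, and 0 to 38 without 1 library. In the combination against particulate they were 1197 with no filter, 306 with DESeq2, 6 with limma-trend on TPM, 4 with quality weights, 0 with only the libraries compared, and 0 to 3257 without 1 library. In the combination against control they were 1480 with limma-trend on TPM, 1026 with only the libraries compared, and 407 to 5137 without 1 library, and in the combination against fucoidan 1993, 1511, and 743 to 5339. In the interaction they were 156 with no filter, 20 with DESeq2, 1 with limma-trend on TPM, and 0 to 865 without 1 library.

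Genes moved back numbered 195 with DESeq2, 511 with no filter, 4 with quality weights, and 0 to 1066 without 1 library. Genes changed by both fucoidan and particulate numbered 16 with DESeq2, 53 with no filter, 190 with quality weights, and 0 to 33 without 1 library. Gene lists called with an estimated correlation numbered 0 in all 6 comparisons. Lists called by camera and not by fry were the ATF4 (adjusted p = 0.101) and mitochondrial mRNA lists (0.194) with particulate, and in the combination against control and against fucoidan the interferon, mitosis, mitochondrial mRNA and ribosomal protein lists (up to 0.364), with autophagy (0.204) against control. Fry called 1 in fucoidan against control, which was the aryl hydrocarbon receptor list (adjusted p = 0.031) and not the cholesterol list (adjusted p = 0.0587). It called 3 in the combination against particulate, the cholesterol, p53 and aryl hydrocarbon receptor lists, and none of the others called by camera there, and 0 in the interaction, and camera called 3 to 10 interaction lists without 1 library.

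In the pairing check, correlations of replicate differences between groups ran from -0.250 to 0.075, so replicates of equal number did not vary together. The lowest were -0.25 between fucoidan and particulate and -0.224 between particulate and the combination. A batch shared by replicates of different number was not tested. With the replicate as a block, 3 genes changed in the combination against particulate and 3 genes were moved back.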

Other observations

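The GC and length tests in this part were chosen before their results were seen, and the level tests and the ABCA1 test were chosen after. Cholesterol synthesis genes were higher with fucoidan both with and without particles. Corrected for GC content and transcript length, the median was 0.78 without particles and 0.97 with them. A single deviating library did not explain it, because the lowest library with fucoidan lay at least 0.75 above the highest matching library without it, against a largest replicate difference of 0.4. The hypothesis of a sterol shortage in cells given fucoidan, which could raise these genes, predicted a lower level of the sterol-sensing LXR target ABCA1, which was at -0.38 ± 0.37 without particles and -0.58 ± 0.36 with them. Sterol shortage and other causes cannot be told apart from these values.

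Matrix, YAP/TEAD and TGF-beta target genes were lower with particulate. After correction for GC content and transcript length the medians were -0.92, -0.9 and -0.63. The uncorrected edgeR medians given above for the matrix and TGF-beta lists were larger in size. The libraries without particles lay at least 0.27 above those with them for the YAP/TEAD list, a narrow margin over its largest replicate difference of 0.241. The gap was 0.624 against 0.266 for the matrix list and 0.559 against 0.22 for TGF-beta targets. Every library with particles lay below every library without them, so a single library did not cause the difference. The biological cause was not tested, and the particles cannot be told apart from their solvent.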
